A study of Mus musculus with 4 samples.

How the data were processed

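Single-nucleus RNA sequencing libraries were made from mouse hippocampus. Per the labels, nuclei were isolated by detergent lysis and an iodixanol cushion, and libraries were prepared with a 10x Genomics droplet kit that reads the 3′ end of transcripts. In such a kit each droplet carries its own barcode, so that reads can be traced to a droplet. Per the series' design text, tissue was taken at day 4 after an injection of kainic acid or saline, and each of the 4 libraries was pooled from 5 mice. Each of the 4 groups therefore has 1 library. Variation between mice cannot be seen in a pool, no group has a replicate, and no test between groups was made.

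Per the submitters' processing notes, reads were processed with Cell Ranger 9.0.1 and the genome build was mm10 (GRCm38). The annotation release, and whether counting used strand, are not given in the sources used here. For each library 2 deposited text lists were used. The barcode list holds 1 barcode of 16 bases per line with a constant suffix and is the raw list, before any selection of nuclei. The gene list holds an identifier, a symbol and a feature type per line. Neither list holds an expression value. The matrices that join genes to barcodes were not analysed here. Reads or molecules per nucleus, the number of nuclei, cell types, the level of Mgll, and the 4 planned expression comparisons (kainic acid against saline within each genotype, and knockout against wild type within each treatment) are therefore not reported. The depth of the libraries is unknown.

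Distinct barcodes were counted per library, and the barcodes shared by each of the 6 pairs of libraries were counted. The sharing that independent lists would give is the product of the lengths of both lists divided by the number of possible barcodes. Before the data were examined, the number of possible barcodes was set to the barcodes seen in any library, with the Lincoln-Petersen estimate (the product of the lengths of both lists of a pair, divided by the barcodes they share) from the remaining pair of libraries as the alternative. A further value was added after the data had been seen. Every barcode was split into a first segment of 7 bases, a middle pair of bases and a last segment of 7 bases. The number of first segments seen with a given middle pair was multiplied by the number of last segments seen with it, and the products were summed. Intervals on shared barcodes are 95% Wilson intervals and cover counting error only. Expected sharing was also summed within classes of GC content, and computed from 2 models of each library on both segments, an additive logistic model and one in which the abundance of a barcode is the product of a value per segment. Neither models joint effects of particular first and last segments. On simulated lists with segment effects and no carried barcodes, the ratio of observed to expected sharing was 1.07 without a model and 1.00 with the logistic model, and it was 1.05 with that model where barcodes had been carried from one library into another. The simulated segment effects had the logistic form themselves, so the 1.00 says nothing about segment effects of another form. The multiplicative model was not simulated.

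The gene lists were matched by identifier to GENCODE release M21, an annotation of GRCm38, and all coordinates given are GRCm38 positions from that annotation, counted from 1. For each of 21 chromosomes, matched genes were taken in the order of the gene list, and each step from a gene to the next was called rising or falling by the gene start. The stretch with the largest excess of falling over rising steps was located. In simulated orders 20 of 20 planted reversed stretches were recovered at their exact ends. The planted stretches were shorter than the one found, lay away from the chromosome ends and held no rising steps. Recovery with rising steps inside a stretch was therefore not simulated. RefSeq gene starts on GRCm38.p6, matched by symbol, served as a second source. The analysis of gene order was chosen after the data had been seen.

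Before the data were examined, 8 gene lists and 15 lists of cell type markers were fixed, with 161 distinct genes. They are pan-reactive, A1-labelled and A2-labelled astrocyte genes, reactive and homeostatic microglial genes, neuronal activity genes, endocannabinoid genes and interferon genes, and markers of astrocytes, microglia, oligodendrocytes, their precursors, excitatory neurons, dentate granule cells, CA1 and CA3 neurons, inhibitory neurons, endothelial cells, pericytes, ependymal cells, choroid plexus, fibroblasts and infiltrating immune cells. The naming rule took Mgll first and made every counted member of these lists eligible. For data without expression values it named Mgll, members with no line or several lines, and features not named as a gene of the annotation. Every member had 1 line, so members named as examples rest on that eligibility alone. Genes named for their place in the chromosome 14 stretch, other than Abhd6, were chosen after their positions had been seen, as were the genes named because they overlap another gene or share a symbol. Computations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.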

Results

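The study set kainic acid against saline in wild-type mice (WT) and in mice lacking Mgll in astrocytes (aKO). Mgll encodes monoacylglycerol lipase, the main enzyme that breaks down the endocannabinoid 2-arachidonoylglycerol in brain. Kainic acid is a glutamate receptor agonist that provokes seizures in rodents. Hippocampal nuclei were profiled at day 4 in 4 libraries, WT-Veh, WT-KA, aKO-Veh and aKO-KA, where Veh is saline and KA is kainic acid. Each library was pooled from 5 mice, and each group had 1 library. Expression values were not analysed here, so no gene or cell type is reported as higher or lower in any group. What follows describes the genes that the libraries were counted over and the barcodes listed for each library.

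The gene list was the same in all 4 libraries and held 33696 genes, each with a mouse Ensembl identifier and each typed as gene expression. No line stood for an added transgene sequence such as a recombinase or a fluorescent reporter. Of these genes 32012 had their identifier in GENCODE M21, among them 21409 of the 22028 protein-coding genes of that annotation. The remaining 1684 identifiers had no entry there. For 2635 matched genes the symbol in the gene list differed from that of the annotation. The list held 13 mitochondrial genes, 248 genes with their identifier in place of a symbol, and 26 symbols that stood on 2 lines each, among them Aldoa, Ddit3, Nrg1 and Nnt. Values looked up by those symbols would mix separate genes.

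Mgll (ENSMUSG00000033174) had 1 line. In GRCm38 it is a protein-coding gene on the plus strand of chromosome 6, from 88724412 to 88828360, a span of 103949 bases. Among the 32012 listed genes with a position in the annotation, no other gene overlapped it on the same strand, and 1, Gm26588, overlapped it on the opposite strand. The 1684 genes without a position could not be checked for overlap with any gene. The deleted part of Mgll is not given in the sources used here, so the gene list does not show whether a 3′ tag of Mgll would report the deletion.

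All 16 endocannabinoid genes had 1 line each. They include other hydrolases of 2-arachidonoylglycerol, Abhd6 on chromosome 14 (8002902 to 8056763) and Abhd12 on chromosome 2 (150832493 to 150904741). Dagla on chromosome 19 (10245265 to 10304877) and Daglb on chromosome 5 (143464584 to 143505942) encode the lipases that make it. Cnr1 on chromosome 4 (33924593 to 33948831) and Cnr2 on the same chromosome (135895394 to 135920207) encode the cannabinoid receptors. Ptgs1 and Ptgs2, the cyclooxygenase genes of prostaglandin synthesis, were also listed. Of the 16 genes, Mgll, Dagla, Daglb and Pparg overlapped a listed gene with a position on the opposite strand, and none overlapped such a gene on the same strand.

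Each gene of the reactive glia lists also had 1 line. This held for the 12 pan-reactive astrocyte genes, such as Gfap, Vim and Serpina3n, the 13 A1-labelled genes, such as C3 and Serping1, and the 12 A2-labelled genes, such as Ptx3 and S100a10. It held as well for the 18 reactive microglial genes, such as Spp1 and Trem2, the 8 homeostatic microglial genes, such as P2ry12 and Tmem119, the 10 activity genes, such as Fos and Arc, and the 8 interferon genes. The 15 sets of cell type markers were likewise complete, and over all lists 161 of 161 genes were present. By GENCODE M21 positions, at least 4 of the 161 genes overlapped another listed gene on the same strand, namely Ugt1a1, Aldh1l1, Cx3cr1 and Fkbp5. Overlap on the opposite strand was found for at least 40 genes, among them Slc1a2, Aqp4, P2ry12, Csf1r and Gad1. Gene bounds, and so these numbers, may differ in the annotation used for counting, whose release is not given. The share of all listed genes with such an overlap was not computed, so the numbers do not show that overlap is particular to the fixed genes. Whether reads from such overlaps were separated by strand is not given in the sources used here.

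Genes on chromosome 14 were not listed in the order of GRCm38. The first 152 matched genes of this chromosome ran backwards, from Gm48099 to Gm2888, and together covered 3030002 to 19282822. In this stretch 135 steps fell and 16 rose by gene start, and 150 fell and 1 rose by gene end. With RefSeq gene starts, available for 115 of the genes, 109 steps fell and 5 rose. The stretch held 109 protein-coding genes. They include Abhd6, the 1 member of the fixed lists in it, the thyroid hormone receptor gene Thrb (17660261 to 18038090), the retinoic acid receptor gene Rarb (16430839 to 16819156) and Fhit (9550092 to 11162035). On the other 20 chromosomes 32 of 30475 steps (0.105%) fell, and the longest falling stretch there held 3 genes.

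**Figure D1:**
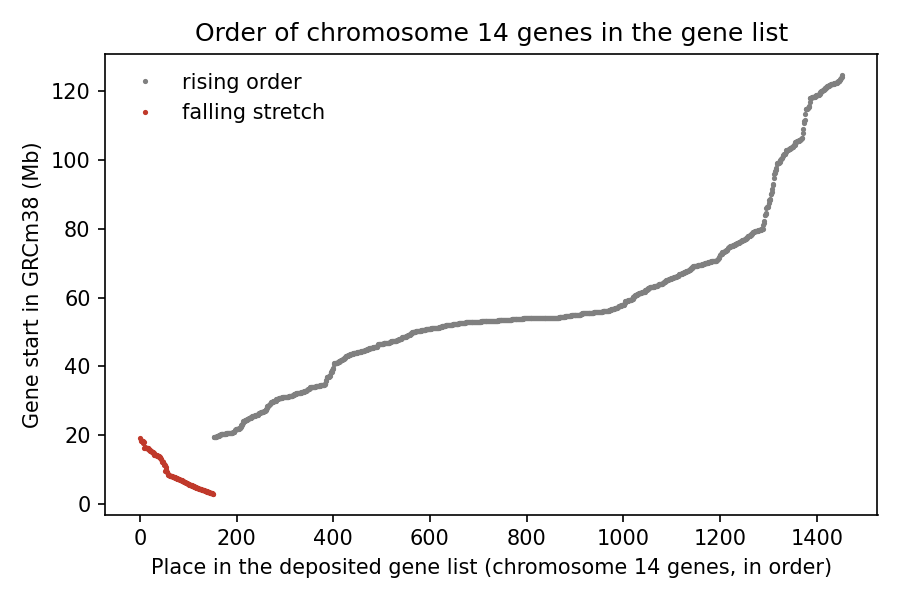
Each point is a chromosome 14 gene, with its place among the matched chromosome 14 genes of the deposited list on the x axis and its GRCm38 start in Mb on the y axis. The 152 genes in red fall at 135 steps and rise at 16, and the genes in grey rise except at 1 step.

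The raw barcode lists held 1975553 barcodes in WT-Veh, 1865864 in WT-KA, 1867474 in aKO-Veh and 1896034 in aKO-KA. No barcode was repeated within a library. WT-KA minus WT-Veh was -109689 barcodes, or -5.55%, and aKO-KA minus aKO-Veh was 28560 barcodes, or 1.53%. Between genotypes, aKO-Veh minus WT-Veh was -108079 barcodes, and aKO-KA minus WT-KA was 30170. With 1 library per group these differences have no replicate check. A raw list includes barcodes without a nucleus, so these are not numbers of nuclei. Whether each listed barcode stands for a droplet was not checked, so they are not given as numbers of droplets either.

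The 4 lists together held 3426799 barcodes. Each was built from 1 of 3840 first segments, 1 of 4 middle pairs of bases and 1 of 3840 last segments, and each middle pair occurred with 960 first and 960 last segments. These parts allow 3686400 barcodes, of which 93.0% were seen in any library, 53.6% in WT-Veh, 50.6% in WT-KA, 50.7% in aKO-Veh and 51.4% in aKO-KA. Libraries shared between 993429 barcodes (WT-KA and aKO-Veh) and 1061916 barcodes (WT-Veh and aKO-KA). Taking the barcodes seen in any library as those possible, as planned, the ratio of observed to expected sharing was 0.972 to 0.977 (95% Wilson intervals between 0.970 and 0.979). That denominator leaves out barcodes seen in no library, so the ratio lies below 1 for independent lists too. With 3686400 possible barcodes, independent lists of these lengths would give 0.945, and all 6 pairs lay above it. With 3686400 as the denominator itself, a choice made after the data had been seen, the ratio was 1.045 to 1.051, where independent lists give 1. On that basis 349882 barcodes were in all 4 libraries, against 260533 for independent lists, and 259601 were in none, against 202470.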

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

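The number of listed barcodes differed in opposite directions between kainic acid and saline. It was lower in WT-KA than in WT-Veh (WT-KA minus WT-Veh -109689) and higher in aKO-KA than in aKO-Veh (aKO-KA minus aKO-Veh 28560). WT-Veh had the longest list of all libraries. Without kainic acid, aKO-Veh minus WT-Veh was -108079, so the contrast between genotypes cannot be told apart from a trait of the WT-Veh library. The difference between the genotypes was not tested, since each group has 1 library and the sequencing depth is unknown, and no explanation was tested.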

How the results depend on the processing

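Removing the barcode suffix left the 4 barcode numbers the same, and ignoring case left 161 of 161 fixed genes in the gene list. Neither could have come out otherwise, because the suffix is constant and every fixed gene already matched with its case. The ratio of observed to expected sharing depended on the number of possible barcodes. With the Lincoln-Petersen estimate from the other pair it was 1.001 for WT-Veh and WT-KA, 0.998 for WT-Veh and aKO-Veh, 0.994 for WT-Veh and aKO-KA, 1.006 for WT-KA and aKO-Veh, 1.002 for WT-KA and aKO-KA, and 0.999 for aKO-Veh and aKO-KA. With the products of the segments seen, chosen after seeing the data, it was 1.048, 1.046, 1.045, 1.051, 1.048 and 1.047 for the same pairs in that order. The Lincoln-Petersen values are 3 reciprocal pairs, centred on 1 by construction, so they cannot show more or less sharing than independent lists. Each only sets the sharing of a pair against that of the remaining pair. The union and the products have different values for independent lists (0.945 and 1), and all pairs lay above these with both. These are not separate checks, since 0.945 itself rests on the 3686400 possible barcodes from the products. Both ratios also differ by the same factor in every pair. The planned union ratio, below 1 in every pair, does not show an excess by itself. Other settings for cell type composition, Mgll in astrocytes, the gene lists per class and the 4 expression comparisons were not run, because expression values were not analysed here. Depth is unknown, and no result has a replicate.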

Other observations

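The tests of gene order, GC content and barcode segments, and the denominator of 3686400, were chosen after the results had been seen. So was the value of 0.945 for independent lists, which is computed from that denominator. The sharing over the union of the lists and the Lincoln-Petersen alternative were planned.

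The reversed order of the first 152 chromosome 14 genes bears on the genome build behind the counts. If the list followed GRCm38 and another annotation release had only moved gene starts, falling steps would be scattered. Instead 135 falling steps lay in 1 stretch, and no stretch on the other 20 chromosomes held more than 3 genes, which argues against that explanation. If the list followed an assembly in which this segment lies the other way round, the GRCm38 end of a gene would act as its start, and the order by gene end would be cleaner than by gene start. By gene end 99.3% of steps fell, against 89.4% by gene start, both with GENCODE M21 bounds. By RefSeq start, available for 115 of the genes, 109 steps fell and 5 rose. RefSeq gene ends were not compared, so the contrast of start and end rests on GENCODE alone. A candidate explanation is therefore that the reference was a later mouse assembly, such as GRCm39, rather than the mm10 of the processing notes. No GRCm39 annotation was used here, so this stays a hypothesis, and its effect on counts was not tested.

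Any pair of libraries shared on average 4.76% more barcodes than independent lists drawn from 3686400 possible barcodes. Over the union of the lists the ratio was 0.972 to 0.977 against 0.945 for independent lists. That 0.945 rests on the same 3686400, so the union ratio adds no separate support. The Lincoln-Petersen alternative cannot show an excess. Barcodes richer in G and C were listed more often: in WT-Veh 47.7% of those with 5 such bases and 58.2% of those with 11 were listed, and in aKO-KA 42.0% and 58.0%. GC content as the whole cause is argued against, since an excess of 4.41% was left within classes of GC content. With the same denominator, a logistic model of how often each first and last segment is listed left 0.920% and a multiplicative model left 0.923%. What was left is 10.9 to 12.4 counting SDs in each pair with either model, where the SD came from the logistic model for both. Neither model therefore accounts for the whole excess, while the segments may account for most of it. Whether the segments in combination account for the whole stays open, because joint effects of particular segments were not modelled and counting error does not cover them. No biological explanation was tested.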
